A study of Mus musculus with 6 samples.

How the data were processed

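Kit-positive cells were isolated from the bone marrow of C57BL/6 mice with CD117 microbeads, kept in medium with FLT3, IL-6, IL-3 and mouse SCF, and transduced on retronectin with retrovirus carrying a control vector or a mutant of CSF3R, the receptor for granulocyte colony-stimulating factor. Transduced cells were sorted by flow cytometry and cultured overnight before total RNA was prepared, and stranded mRNA libraries were made with the TruSeq kit, per the labels' protocols. There were 6 libraries, 1 for each of vector, W791, Q741, T618I, T618I/Q741 and T618I/W791. The labels name constructs and not separate animals or cultures of a construct.

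The authors deposited a single table with a gene symbol and a value per library. Its header names no unit; the values were read as FPKM (fragments per kilobase of transcript, scaled to sequencing depth), the unit that Cufflinks writes, since the values carry decimals and the deposited columns sum to between 439505 and 492025, which fits neither counts nor TPM. TopHat and Cufflinks and the genome build mm10 are named in the submitters' processing notes. Tool versions, the gene annotation and the use of strand in quantification are not given in the sources used here. Column abbreviations for the double mutants were matched to the titles by their letters.

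The table held 23444 rows. In 27 rows the symbol had been turned into a date, so these rows were left out, which kept 23417 rows with a symbol. Values were taken as log2(FPKM + 1) without further scaling, and genes at 1 FPKM or more in at least 2 libraries were tested, which left 11188 genes. All fold changes are therefore on the log2(value + 1) scale and understate the change of genes with low values. A value at exactly 0 in a table without counts can be a failed estimate, so such genes are described as listed at 0, with each library's value and no fold against a group at 0.

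Depth per library is not stated in the table. It was approximated from the smallest steps among the values of 3394 genes with a single transcript, using transcript lengths of GENCODE M21 (the same build), which gave, about 20.0 M fragments for Q741, 24.3 M for T618I/Q741, 19.5 M for T618I, 20.7 M for T618I/W791, 19.5 M for W791 and 41.7 M for vector. At those depths 1 FPKM of a 1 kb transcript corresponds to between 19.5 and 41.7 fragments. Of the tested symbols, 95.0% matched an M21 symbol exactly; coordinates are 1-based on mm10 from that annotation.

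Groups followed the design text of the series: T618I-containing constructs (T618I, T618I/Q741 and T618I/W791; n = 3), truncations alone (W791 and Q741; n = 2) and vector (n = 1). Limma 3.58.1 in R 4.3.3 fitted 3 group means to all 6 libraries with a mean-variance trend in the prior variance, leaving 3 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each construct was sequenced once, so every SD and p-value in the class comparisons measures the spread between different constructs of a class, library noise included. The lone vector library was assumed to vary like the others. Differences between single libraries (T618I added to vector, Q741 or W791, and truncations added to T618I) have no replicate check and were described by a 2-fold threshold without a test. No construct carried the unmutated receptor. Any comparison with vector therefore mixes introducing a receptor with its mutation, as do fits that pair or group vector with the truncations. For pairs with a common control, the overlap without any effect was simulated in 100 runs of 3 unchanged libraries, and in each direction as many genes were taken by rank as the observed lists held. Per-gene spreads followed either the difference between W791 and Q741 or the residual spread of the class fit. This was chosen after simulations matched only on the total number of genes per pair had given lists larger than some of the observed ones. For the comparisons of T618I-containing libraries with truncations and with vector, which use the same 3 libraries, 6 unchanged libraries were simulated and fitted in 100 runs, and lists of the called sizes were taken by rank of the moderated statistic.

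The design, the tests, the gene lists, the rule for named genes and the alternatives listed below, except the one marked as added, were fixed before the data were examined. The rule names the 12 highest and 12 lowest folds among genes past the threshold whose class values did not overlap, with 1 FPKM or more in the higher class, leaving out symbols of predicted genes (Gm and Rik), microRNAs, small nucleolar RNAs, small nuclear RNAs, ribosomal pseudogenes and olfactory receptors. Where fewer than 12 passed, it adds the genes with the widest gap between classes among those at 5 FPKM or more in the higher class, which are given as values. It also names Csf3r, every member of the lists, and the 3 highest and 3 lowest differences of each pair of libraries with 5 FPKM or more in either library. Genes named outside the rule are marked as chosen after their values were seen.

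Of 25 fixed gene lists, 24 had at least 3 tested members; no gene of the mitochondrial genome list was measured in the rows used here. Lists were tested in the class comparison with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Fry was read by its directional test. Its mixed test, which takes members moving either way, was not used for calls. For each pair of libraries the median of a list was placed as a percentile among 10000 random lists of the same size matched on mean expression, as a description of those libraries. The class test was tried on simulated normal data of 11188 genes, with spreads drawn from the fitted prior and 200 changed genes in each of 20 runs. It recovered 25.2% of genes changed by 1 on the log2 scale, 80.7% at 2, 92.2% at 3 and 98.9% at 5, and 5.38% of its calls were unchanged genes. The simulated genes were independent and had the same spread in each class. The T618I-containing libraries differed more among themselves than W791 and Q741 did, so these shares may not hold for the data.

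Alternatives covered the pseudocount, the filter on low values, quantile normalization, median-ratio scaling, the prior variance without a trend, additive fits with the tail as a block, other fold thresholds and leaving out each library of the mutant classes in turn. A comparison of T618I present against absent, with vector counted among the absent libraries (3 against 3), was added after seeing the data, as was the estimated correlation in it and in fits with a library left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and figures.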

Results

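RNA was sequenced from mouse Kit-positive bone marrow cells that carried a control retrovirus or a mutant of CSF3R, the receptor for granulocyte colony-stimulating factor. The mutants held the membrane-proximal change T618I, the tail truncation Q741 or W791, or T618I together with either truncation, with 1 library per construct. The design text of the series classes T618I alone and the double mutants as leukemogenic and the truncations alone as non-leukemogenic. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, took up 3.91% of all FPKM with T618I, 6.02% with T618I/Q741 and 5.15% with T618I/W791, against 0.446% with vector, 0.642% with W791 and 0.588% with Q741. S100a8 had the highest value of any gene in each T618I-containing library, and Lyz2, which encodes lysozyme, had it in each of the others.

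Libraries without T618I resembled each other closely. The correlation of log2 values was 0.990 between vector and W791, 0.985 between vector and Q741 and 0.987 between the truncations. T618I correlated with vector at 0.956, T618I/Q741 with Q741 at 0.931 and T618I/W791 with W791 at 0.941. The double mutants were the furthest apart of the T618I-containing libraries, at 0.925, with 1506 genes differing by 2-fold or more. The first principal component carried 48.5% of the variance and set T618I (16.6), T618I/Q741 (30.7) and T618I/W791 (30.3) apart from vector (-30.3), Q741 (-26.6) and W791 (-20.7). The next component carried 32.6% and set T618I/Q741 (36.7) against T618I/W791 (-38.3).

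**Figure D1:**
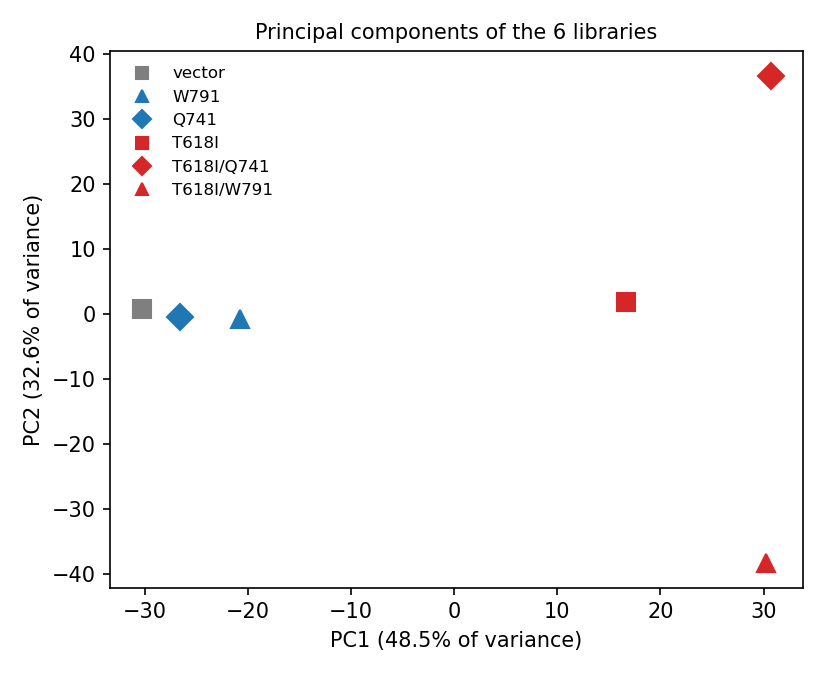
Position of the 6 libraries on the first principal components of log2(FPKM + 1), with the share of variance of each component on its axis; colour gives the class and marker shape the tail.

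Endogenous mouse Csf3r (chromosome 4, 126024550 to 126044440) was listed at 53.1 FPKM with vector, 52.8 with W791, 56.7 with Q741, 69.4 with T618I, 95.9 with T618I/Q741 and 38.8 with T618I/W791. Between the mutant classes its difference was 0.22 ± 0.38 on the log2 scale (SE, adjusted p = 0.976). Whether reads from the introduced receptor entered this gene's value is not given in the sources used here.

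The stefin A genes, S100a8, S100a9 and Lipg rose in T618I-containing cells, and Igfbp7 fell. At adjusted p below 0.05, 20 genes were higher and 2 were lower in T618I-containing libraries (n = 3) than in truncation libraries (n = 2). The largest group was the stefin A cluster of cysteine protease inhibitors on chromosome 16 between 36156811 and 36455392, which held 9 of the 22 genes. Calprotectin followed, with S100a8 up 7.62-fold from 1750 ± 54.5 to 13483 ± 2400 FPKM and S100a9 up 10.5-fold from 991 ± 168 to 10730 ± 3293 FPKM (mean ± SD).

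In the stefin A cluster, Stfa1 went from 4.19 ± 1.54 to 1350 ± 283 FPKM, a log2 difference of 8.03 ± 0.27 (SE, adjusted p = 0.00219). BC100530 went from 5.31 ± 3.31 to 2956 ± 1060 FPKM (8.91 ± 0.45, adjusted p = 0.00685). Stfa2l1 went from 3.57 ± 2.78 to 1202 ± 550 FPKM (8.09 ± 0.51, adjusted p = 0.00892) and Stfa3 from 3.01 ± 1.88 to 861 ± 408 FPKM (7.70 ± 0.53, adjusted p = 0.0128). Stfa2 was at 601, 1960 and 1115 FPKM with T618I, T618I/Q741 and T618I/W791, at 0.538 with W791 and listed at 0 with Q741, with adjusted p = 0.00685. BC117090 was at 11.9, 13.2 and 12.2 FPKM with T618I, T618I/Q741 and T618I/W791 and was listed at 0 with W791, Q741 and vector (adjusted p = 0.00219). Gm5483, Gm5416 and 2010005H15Rik, chosen after their values were seen, are the other members past the threshold. Copies in this cluster are near-identical, so the division of reads among its genes is uncertain. The 9 called genes of the cluster summed to 6819, 12443 and 11589 FPKM with T618I, T618I/Q741 and T618I/W791. They summed to 33.4 with W791, 14.9 with Q741 and 16.4 with vector. Genes of the region that were not called are left out of these sums.

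Outside the cluster, S100a8 (chromosome 3, 90668978 to 90670035) rose by 2.93 ± 0.18 on the log2 scale (adjusted p = 0.00786) and its neighbour S100a9 (90692632 to 90695721) by 3.40 ± 0.30 (adjusted p = 0.0279). Lipg, which encodes endothelial lipase, rose 56.7-fold from 0.388 ± 0.0178 to 83.6 ± 36.3 FPKM (5.82 ± 0.41, adjusted p = 0.0128). Asprv1, an aspartic protease gene, rose from 0.275 ± 0.134 to 24.7 ± 12.7 FPKM (4.22 ± 0.41, adjusted p = 0.0421). Il1bos, transcribed antisense to Il1b, rose from 0.493 ± 0.596 to 12.2 ± 2.95 FPKM (3.18 ± 0.32, adjusted p = 0.0474), while Il1b itself was at 76.1, 68.0 and 18.8 FPKM with T618I, T618I/Q741 and T618I/W791 and at 70.3 and 66.0 with W791 and Q741 (adjusted p = 0.924). Ankrd22 rose from 0.521 ± 0.0745 to 9.06 ± 2.66 FPKM (2.69 ± 0.24, adjusted p = 0.0309). Chosen after their values were seen, the Schlafen family gene Slfn4 rose from 1.93 to 18.1 FPKM (adjusted p = 0.0133) and the metallothionein gene Mt2 from 74.0 to 402 (adjusted p = 0.0421). Also chosen that way, the IL-36 gamma gene Il1f9 rose from 5.85 to 30.8 (adjusted p = 0.0200), the triglyceride synthesis gene Dgat2 from 9.35 to 41.8 (adjusted p = 0.0148) and Sapcd1 from 1.20 to 9.88 (adjusted p = 0.0150).

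**Figure D2:**
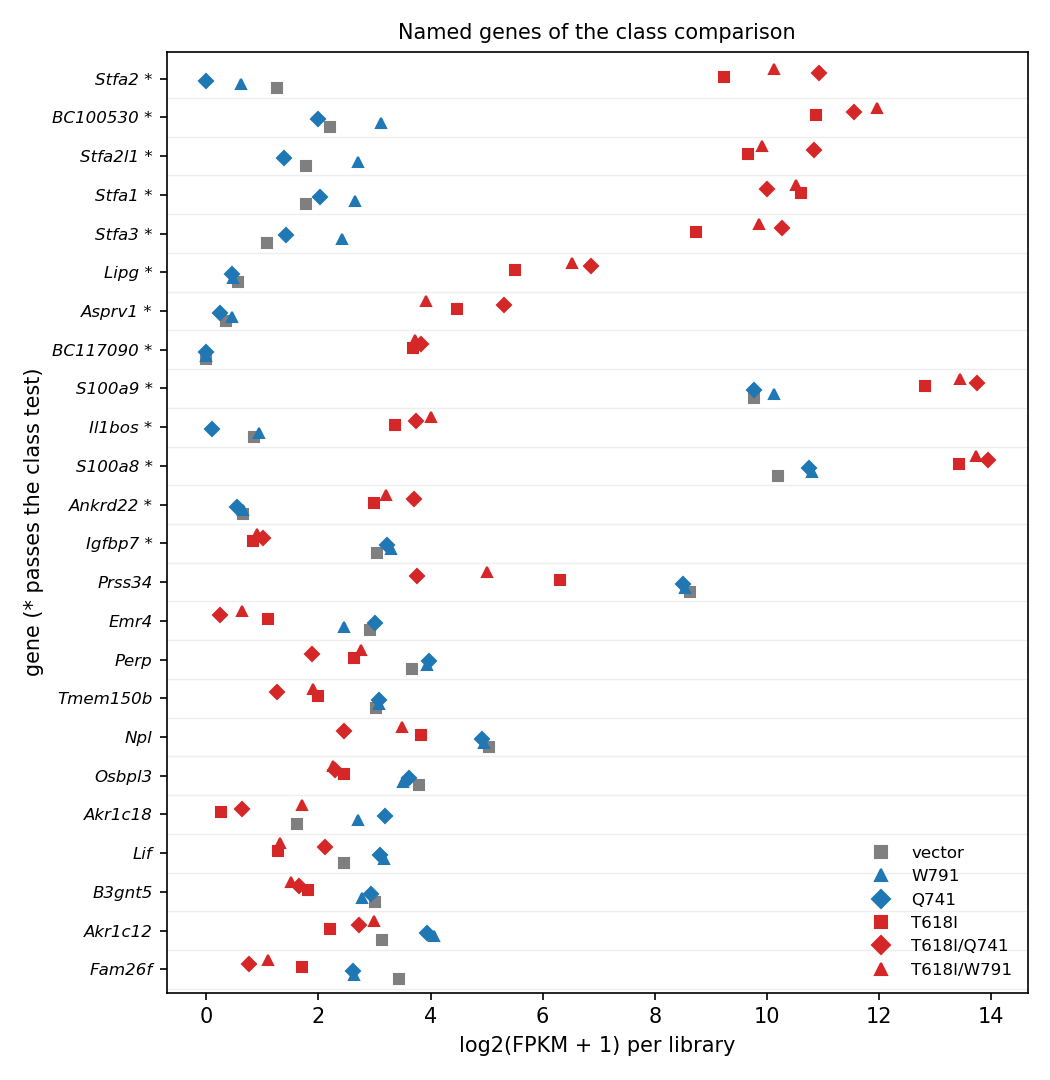
FPKM per library of the genes named in the comparison of T618I-containing with truncation libraries, on the log2(FPKM + 1) scale; each point is a library.

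Igfbp7, which encodes a secreted binding protein of insulin-like growth factors, fell from 8.55 ± 0.327 to 0.893 ± 0.127 FPKM, 5.05-fold (adjusted p = 0.00786). The small nucleolar RNA gene Snord15b, chosen after its values were seen, was listed at 0 in all T618I-containing libraries and at 5.90, 5.23 and 7.78 FPKM with W791, Q741 and vector. RNAs this short are poorly captured by mRNA libraries. Among genes with the widest gap below the truncation libraries that did not pass, the basophil protease gene Prss34 was at 40.8 ± 34.1 against 367 ± 5.47 FPKM (adjusted p = 0.259). The macrophage receptor gene Emr4 was at 0.637 ± 0.486 against 5.77 ± 1.84 (adjusted p = 0.157). Osbpl3 was at 4.08 ± 0.386 against 10.8 ± 0.608 FPKM (adjusted p = 0.0729). B3gnt5 was at 2.17 ± 0.344 against 6.27 ± 0.557 (adjusted p = 0.112) and Npl at 9.32 ± 4.45 against 29.6 ± 0.331 (adjusted p = 0.340). Perp, Tmem150b, Lif and Akr1c12 each had adjusted p = 0.240, Akr1c18 0.299 and Fam26f 0.259. In the fit with the tail as a block over 3 pairs 6 of these genes passed as lower: Fam26f (adjusted p = 0.0181), Osbpl3 (0.0265), B3gnt5 (0.0317), Emr4 (0.0360), Prss34 (0.0469) and Akr1c12 (0.0469). In the additive fit over the 2 truncation pairs alone, Npl (adjusted p = 0.00813), Perp (0.0194), Tmem150b (0.0219), Akr1c18 (0.0227) and Lif (0.0385) passed as lower. Akr1c12 (0.0932) did not pass there. These additive fits leave fewer residual degrees of freedom than the 3 of the class fit, so their spreads lean more on the prior. The genes they add had not passed the class test.

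Unadjusted p lay below 0.05 for 465 higher and 544 lower genes of 11188. Libraries of the classes did not overlap for 1032 genes with higher and 2356 with lower values in T618I-containing cells, 30.3% of the genes where chance gives 20%. The balance of higher and lower genes depended on scaling: with median-ratio scaling 571 genes were higher and 364 lower at unadjusted p below 0.05, and 1576 and 1516 did not overlap, 27.6% of the genes. With W791 left out 6 genes were higher and 0 lower, with Q741 left out 2 and 0, and with T618I left out 11 and 1. Without the filter on low values 3 were higher.

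Neutrophil and globin genes joined the list when vector was counted with the truncations, a comparison of T618I present with T618I absent (3 against 3) that was chosen after seeing the data. It gave 75 higher and 22 lower genes, all 22 genes above among them. A fit that blocked on the tail gave 83 higher and 36 lower, with 66 genes passing in both. Both fits use the same libraries and give each gene the same log2 difference. Only the estimated spread differs, so the shared direction is no separate evidence. In the 3 against 3 comparison the neutrophil genes Lcn2 (2.70 ± 0.29, adjusted p = 0.0172), Cd177 (3.66 ± 0.43, adjusted p = 0.0223), Retnlg (4.69 ± 0.68, adjusted p = 0.0407), Mmp9 (3.72 ± 0.57, adjusted p = 0.0494) and Fpr1 (2.68 ± 0.24, adjusted p = 0.00749) rose. Cebpe, a transcription factor gene of late granulocyte maturation, rose too (1.55 ± 0.20, adjusted p = 0.0310). The globin genes Hbb-bt (6.06 ± 0.62, adjusted p = 0.0133), Hba-a2 (5.04 ± 0.59, adjusted p = 0.0219) and Hbb-b1 (6.25 ± 0.89, adjusted p = 0.0385) rose as well. Lower genes included Emr4 (-2.12 ± 0.26, adjusted p = 0.0236), Il4 (-1.26 ± 0.14, adjusted p = 0.0186), Bcl2 (-1.24 ± 0.17, adjusted p = 0.0367), Osbpl3 (-1.30 ± 0.12, adjusted p = 0.00842), Vcam1 (-1.03 ± 0.13, adjusted p = 0.0236) and Gbp3 (-1.01 ± 0.14, adjusted p = 0.0331). With the tail as a block Retnlg (adjusted p = 0.0504), Mmp9 (0.0538) and Vcam1 (0.0627) did not pass, and the other genes named here did. Fpr1, Bcl2 and Vcam1 were chosen after their values were seen.

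Of the 24 gene lists tested between the mutant classes, 12 were called at the preset correlation and 0 with an estimated correlation or with fry's directional test. Fry's mixed test gave adjusted p = 0.00588 for mast cell and basophil genes and 0.0153 for eosinophil genes. For secondary and tertiary granule genes it gave 0.0415, and the other lists lay above 0.05. Secondary and tertiary granule genes were higher, with 19 of 21 above 0 and a median log2 difference of 1.85 (adjusted p = 2.14e-16, adjusted p = 0.600 with an estimated correlation). With T618I/Q741 left out the median was 0.90. Over all genes 2 of them passed, S100a8 and S100a9. Adjusted over the list alone 10 were higher, among them Lcn2 (918 ± 373 against 148 ± 9.65 FPKM), Cd177 (52.9 ± 33.1 against 2.77 ± 0.618) and Mmp9 (26.8 ± 24.2 against 0.754 ± 0.648). The specific granule genes Ngp and Ltf differed between the T618I-containing libraries. With T618I, T618I/Q741 and T618I/W791, Ngp was at 251, 2988 and 704 FPKM and Ltf at 23.3, 320 and 95.8. Primary granule genes were not called (10 of 15 above 0, median 0.03, adjusted p = 0.395), but were called higher in the 3 against 3 comparison (median 0.18, adjusted p = 0.0434, adjusted p = 0.522 with an estimated correlation). Adjusted over the list alone Mpo (569 ± 17.5 against 820 ± 27.3 FPKM) and Ctsc (212 ± 16.4 against 319 ± 16.1) were lower. Granulocytic transcription factors were not called either (6 of 12 above 0, median -0.04, adjusted p = 0.369), with Cebpe alone passing over the list, at 24.4 ± 6.37 against 8.10 ± 0.338 FPKM.

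**Figure D3:**
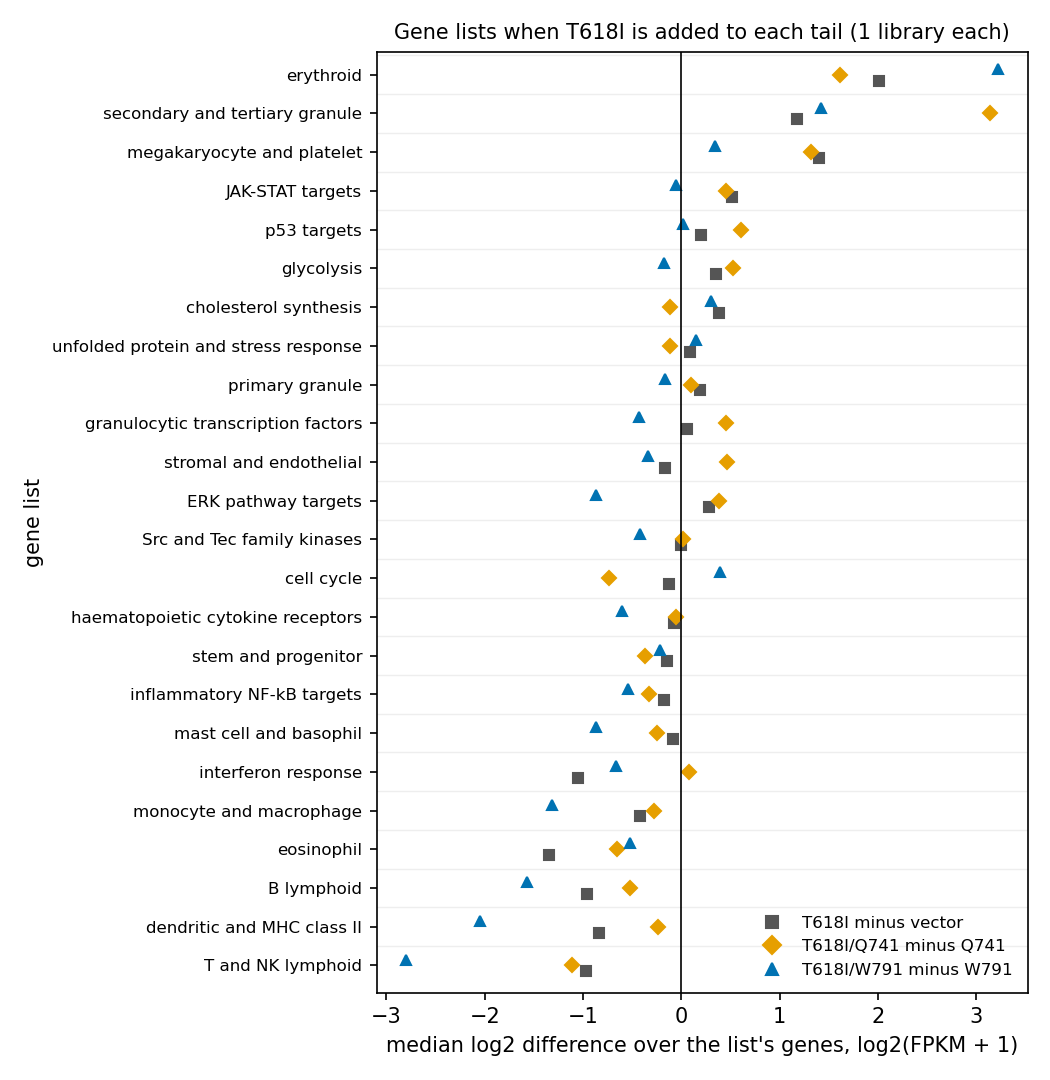
Median log2 difference of each gene list when T618I was added to vector, Q741 or W791; each point is a pair of libraries.

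Erythroid genes were higher in all 16 of 16 cases, with a median log2 difference of 2.17 (adjusted p = 2.89e-20, adjusted p = 0.600 with an estimated correlation). Over all genes 0 of them passed, and over the list alone 13. In the fit with the tail as a block over 3 pairs 6 passed over all genes: Gata1, Klf1, Epor, Hba-a2, Hbb-bt and Hbb-b1. Hbb-bt stood at 193 ± 179 against 1.14 ± 0.177 FPKM, the erythroid transcription factor gene Klf1 at 9.06 ± 6.81 against 0.829 ± 0.171 and Gata1 at 27.5 ± 8.95 against 10.1 ± 4.14. Copies of the alpha and beta globin genes share reads, so single globin values are uncertain. Megakaryocyte and platelet genes were above 0 in 14 of 14 cases (median 1.13, adjusted p = 8.01e-11, adjusted p = 0.600 with an estimated correlation), with 0 passing over the list alone. The Q741 library, 1 of the 2 truncation libraries, was itself low for this list, with a median of -1.04 against vector, 8 of 14 members lower by 2-fold or more and percentile 0 of matched random lists, while W791 had a median of 0.23. The class median was 0.48 with Q741 left out and 1.78 with W791 left out. Against vector the T618I-containing libraries had a median of 0.72 (adjusted p = 7.14e-06, adjusted p = 0.433 with an estimated correlation). The platelet chemokine gene Pf4 stood at 1191 ± 463 against 375 ± 245 FPKM. Mast cell and basophil genes were not called in either direction (5 of 17 above 0, median -0.34, adjusted p = 0.434). Adjusted over the list alone the mast cell protease gene Mcpt1 and the granzyme gene Gzmb were higher (Gzmb 200 ± 107 against 40.3 ± 10.2 FPKM). Prss34 and Il4 were lower (Il4 1.08 ± 0.212 against 3.68 ± 0.0630). With T618I left out this list was called lower (adjusted p = 0.00924, adjusted p = 0.705 with an estimated correlation). Eosinophil genes were lower (5 of 7 below 0, median -0.73, adjusted p = 0.0139, adjusted p = 0.609 with an estimated correlation), with Prg2 and Prg3 lower over the list alone. Adjusted p was 0.159 with T618I left out and 0.0737 in the 3 against 3 comparison.

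Monocyte, dendritic cell and interferon genes were lower as class medians. On adding T618I to Q741 their medians were -0.28, -0.24 and 0.07 (percentiles 10.9, 19.7 and 99.3 of matched random lists). On adding it to W791 they were -1.31, -2.05 and -0.67 (percentile 0 each). Monocyte and macrophage genes were below 0 in 19 of 20 cases (median -0.57, adjusted p = 0.00193, adjusted p = 0.609 with an estimated correlation). Examples were Irf8 (28.3 ± 11.2 against 57.6 ± 0.732 FPKM) and Csf1r (160 ± 63.8 against 275 ± 12.6). Over the list alone 0 passed, and adjusted p was 0.466 with T618I/W791 left out. Dendritic and MHC class II genes were below 0 in 13 of 13 cases (median -0.91, adjusted p = 0.000350, adjusted p = 0.609 with an estimated correlation), with Siglech and Ly6d lower over the list alone and a median of -0.44 with T618I/W791 left out. Cd74, the invariant chain gene, was at 465 ± 248 against 839 ± 85.1 FPKM. Interferon response genes were below 0 in 27 of 30 cases (median -0.38, adjusted p = 0.000350, adjusted p = 0.609 with an estimated correlation), with Ifit2, Ifit3 and Gbp3 lower over the list alone. With T618I/W791 left out the median was -0.18 and adjusted p = 0.104. Inflammatory NF-kB targets were below 0 in 17 of 21 cases (median -0.41, adjusted p = 0.00725, adjusted p = 0.609 with an estimated correlation), such as Ccl3 (70.4 ± 13.4 against 120 ± 1.19 FPKM). Over the list alone 0 passed, and adjusted p was 0.218 with T618I/W791 left out. The B lymphoid list (0 of 4 above 0, median -0.68, adjusted p = 0.0566) and the T and NK list (0 of 3, median -1.54, adjusted p = 0.0670) had few tested members and were not called. With T618I left out adjusted p was 0.0123 and 0.0144 (adjusted p = 0.705 each with an estimated correlation), and with Q741 left out 0.0173 and 0.0159 (adjusted p = 0.715 each with an estimated correlation).

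JAK-STAT targets were called higher between the classes (14 of 20 above 0, median 0.11, adjusted p = 0.00459, adjusted p = 0.600 with an estimated correlation), with Gadd45g alone passing over the list (29.1 ± 6.10 against 9.54 ± 2.20 FPKM). With T618I/Q741 left out adjusted p was 0.261. Against vector the median of this list was 0.58, with 17 of 20 above 0 (adjusted p = 4.66e-07, adjusted p = 0.433 with an estimated correlation). Glycolysis genes (16 of 19 above 0, median 0.13, adjusted p = 0.00261, adjusted p = 0.609 with an estimated correlation) were called higher, as were p53 targets (10 of 15, median 0.24, adjusted p = 0.00725, adjusted p = 0.600 with an estimated correlation). Cholesterol synthesis genes (13 of 18, median 0.09, adjusted p = 0.0104, adjusted p = 0.609 with an estimated correlation) were called higher too, and 0 genes passed over any of these lists alone. Glycolysis (adjusted p = 0.370) and p53 targets (adjusted p = 0.261) lost the call with T618I/Q741 left out, glycolysis also under quantile normalization (adjusted p = 0.0749), and cholesterol synthesis (adjusted p = 0.0876) with T618I/W791 left out. With T618I/Q741 and T618I/W791 left out in turn, the medians were -0.02 and 0.32 for JAK-STAT targets, 0.01 and 0.29 for glycolysis and 0.25 and -0.00263 for cholesterol synthesis. ERK pathway targets (5 of 19 above 0, median -0.19, adjusted p = 0.715), Src and Tec family kinases (6 of 14, median -0.09, adjusted p = 0.559) and haematopoietic cytokine receptors (7 of 17, median -0.22, adjusted p = 0.875) were not called. The class median of the ERK targets was taken over pairs that went opposite ways, with medians of 0.38 on adding T618I to Q741 and -0.86 on adding it to W791. Stem and progenitor genes (6 of 18, median -0.13, adjusted p = 0.847), the unfolded protein and stress response (7 of 16, median -0.04, adjusted p = 0.257) and the stromal and endothelial genes (2 of 3, median 0.26, adjusted p = 0.395) were not called either. Cell cycle genes were not called (8 of 28 above 0, median -0.18, adjusted p = 0.796), but were called higher with T618I/Q741 left out (median 0.12, adjusted p = 0.0155, adjusted p = 0.820 with an estimated correlation) and lower with T618I/W791 left out (median -0.41, adjusted p = 0.00174, adjusted p = 0.669 with an estimated correlation).

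Against vector, stefin A genes and S100a8 were higher and Igfbp7 lower in T618I-containing cells. There were 15 higher and 3 lower genes, with unadjusted p below 0.05 for 378 higher and 574 lower genes. Of the called genes, 14 higher and 2 lower were also called between the mutant classes, a comparison that uses the same 3 T618I-containing libraries. Simulated unchanged libraries with called lists of these sizes shared 1.72 higher and 0.16 lower genes on average (at most 4 and 2 over 100 runs), and unrelated lists would share 0.0268 and 0.000536. As these libraries are common to both, the agreement is not independent evidence. S100a8 rose from 1178 FPKM by 3.50 ± 0.22 on the log2 scale (adjusted p = 0.0161), Stfa1 by 8.59 ± 0.35 (adjusted p = 0.00761), Lipg by 5.73 ± 0.51 (adjusted p = 0.0410), and Igfbp7 fell by 2.13 ± 0.18 (adjusted p = 0.0333). Called here alone was 1100001G20Rik, a whey acidic protein family gene chosen after its values were seen, at 95.6 FPKM with vector and 413, 512 and 570 with T618I, T618I/Q741 and T618I/W791 (2.36, adjusted p = 0.0446). The other was Siglech, a plasmacytoid dendritic cell receptor gene at 8.80 FPKM with vector, 0.465 with T618I, 0.0973 with T618I/Q741 and listed at 0 with T618I/W791 (adjusted p = 0.0410). With 1 vector library this contrast rests on that library. It also mixes introducing a receptor with its mutation, as no construct carried the unmutated receptor. The counts were 6 higher and 0 lower with Q741 left out, 9 and 0 with W791 or T618I left out, and 28 and 6 with T618I/W791 left out.

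The truncations alone differed from vector by 0 genes with limma, at 73 genes with unadjusted p below 0.05 (27 higher, 46 lower) and a smallest adjusted p of 1. The fit holds a single spread per gene for all classes, so the T618I-containing libraries enter it. Those differed from each other by 2-fold or more in 387 to 1506 genes, against 80 between W791 and Q741. The test therefore had little power, and 0 calls do not show that the truncations match vector. Without the filter on low values 9 genes were called. In single libraries the helix-loop-helix gene Id3 had the highest difference, at 56.2 FPKM with Q741 and 56.1 with W791 against 2.45 with vector. Dntt, the terminal transferase gene of early lymphoid cells, was at 1.01 FPKM with Q741 and 1.70 with W791 against 16.4 with vector. With Q741 the apolipoprotein gene Apoe was at 97.7 against 384 FPKM and the interferon-inducible gene Ifi27l2a at 29.7 against 123, and Arg1 was at 7.13 against 1.73. With W791 the non-coding RNA gene Snhg9 was at 17.8 against 2.25 FPKM and Rnaset2a at 0.581 against 6.28. At 2-fold or more Q741 differed from vector in 17 higher and 92 lower genes and W791 in 30 higher and 34 lower, sharing 13 and 24. Unrelated lists of these sizes would share 0.0456 and 0.280 genes. Simulated unchanged libraries with a common control and lists of these sizes in each direction shared 8.62 and 19.8 on average (at most 14 and 26 over 100 runs) with spreads taken from the difference between W791 and Q741. With the residual spreads of the class fit they shared 6.45 and 14.8 (at most 11 and 22). The lone vector library could not be split, so the excess over these values is not to be read as a shared effect.

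The stefin A genes were higher when T618I was added to vector, Q741 or W791. Vector carries no introduced receptor, so the vector pair also holds the effect of introducing a receptor. At 2-fold or more, 305 genes were higher and 142 lower with T618I on vector, 530 and 211 on Q741, and 262 and 477 on W791, in pairs of single libraries without a test. Both truncation pairs, which share no library, had 155 higher and 89 lower genes in common, where unrelated lists would share 12.4 and 8.996. That expectation takes each gene as equally likely to reach 2-fold, so genes with a large spread would raise it. No simulation with per-gene spreads was run for these pairs. In all 3 pairs 116 higher and 38 lower genes were common. The highest differences were those of Stfa1 (2.44 to 1553 FPKM), BC100530 (3.64 to 1873) and Mcpt1 (0.147 to 444) on vector. On Q741 they were Stfa2, listed at 0 with Q741 and at 1960 FPKM with T618I/Q741, BC100530 (2.97 to 3006) and Stfa2l1 (1.61 to 1832), and on W791 Stfa2 (0.538 to 1115), BC100530 (7.66 to 3990) and Hbb-b1 (0.0480 to 441). The lowest differences were those of Dntt (16.4 to 0.860 FPKM), the macrophage lectin gene Mgl2 (16.7 FPKM with vector, log2 difference -2.83) and Siglech (8.80 to 0.465) on vector. Prss34 was among them on Q741 (363 to 12.6) and on W791 (371 to 31.1), and the basophil gene Mcpt8 on Q741 (678 to 93.7). Eif3j2 on Q741 (21.2 to 0.374 FPKM) and Eif3j1 on W791 (32.2 to 0.132) also had low differences. These paralogs moved against each other: summed, they were at 37.2 FPKM with Q741, 20.6 with T618I/Q741, 33.7 with W791 and 51.4 with T618I/W791. Actr3 was listed at 0 with T618I/W791 and at 272 FPKM with W791, which in so widely expressed a gene can be a failed estimate.

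**Figure D4:**
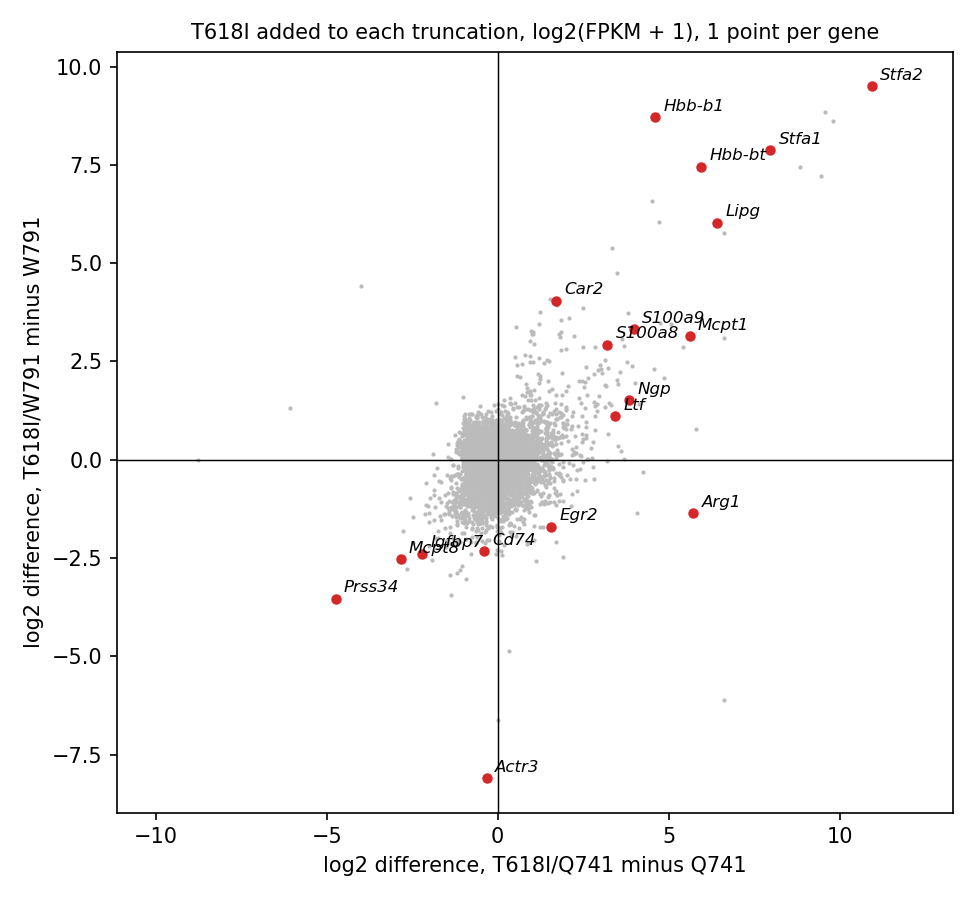
Log2 difference on adding T618I to Q741 against that on adding it to W791 for the tested genes, with named genes labelled; each point is a gene.

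Lists followed the same pairs. On vector, Q741 and W791 the median of secondary and tertiary granule genes was 1.18, 3.14 and 1.42, and that of erythroid genes 2.01, 1.61 and 3.22, each at percentile 100 of matched random lists. Megakaryocyte genes had medians of 1.40, 1.32 and 0.34 (percentiles 100, 100 and 99.6), where the Q741 library had a median of -1.04 against vector. Interferon response genes had -1.05, 0.07 and -0.67 (percentiles 0, 99.3 and 0), without a test of the difference between pairs. Monocyte genes had -0.42, -0.28 and -1.31 (percentiles 0, 10.9 and 0), and dendritic and MHC class II genes -0.84, -0.24 and -2.05 (percentiles 0, 19.7 and 0). Cell cycle genes had -0.13, -0.74 and 0.39 (percentiles 3.43, 0 and 100), with 28 of 28 below 0 on Q741 and 27 of 28 above 0 on W791, and ERK pathway targets 0.28, 0.38 and -0.86 (percentiles 99.99, 99.99 and 0).

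Mast cell and megakaryocyte genes were lower in both double mutants than with T618I alone, in single libraries without a test. Both comparisons subtract the same T618I library, so a property of that library alone would give the same agreement. Relative to T618I alone, T618I/Q741 had 223 genes higher and 164 lower by 2-fold or more and T618I/W791 had 112 and 346, with 25 and 59 in common. Unrelated lists would share 2.23 and 5.07. Unchanged libraries simulated with a common control and lists of these sizes in each direction shared 58.3 and 87.5 on average with spreads taken from the difference between W791 and Q741, and 47.5 and 75.6 with the residual spreads of the class fit. The observed overlap lay below the lowest of 100 runs in each direction (47 and 73, 35 and 60), so it is not to be read as a shared effect. Mast cell and basophil genes had medians of -1.35 with Q741 and -1.31 with W791 (percentile 0 each), with Mcpt1 at 444 FPKM with T618I, 65.4 with T618I/Q741 and 12.3 with T618I/W791. Megakaryocyte genes had medians of -0.99 and -0.93 (percentile 0 each). Without T618I the truncations were unlike each other for megakaryocyte genes, with medians against vector of -1.04 for Q741 and 0.23 for W791. For mast cell and basophil genes those medians were -0.25 and -0.04. The double mutants lay on opposite sides of T618I alone for erythroid genes, with medians of -0.61 and 1.39 (percentiles 0 and 100), and for cell cycle genes, with medians of -0.59 and 0.52 (percentiles 0 and 100). Secondary and tertiary granule genes were above T618I alone in both, with medians of 1.45 and 0.30 (percentiles 100 and 99.8). The highest differences were those of Arg1 (23.7 to 430 FPKM), Ltf (23.3 to 320) and Eif3j1 (0.0769 to 20.2) with T618I/Q741, and the beta globin genes Hbb-b1 (53.1 to 441), Hbb-bs (5.44 to 42.9) and Hbb-bt (59.9 to 396) with T618I/W791. The lowest differences were those of Eif3j2 (33.2 to 0.374), Serpina3b (18.2 to 1.57) and the potassium channel gene Kcnj5 (11.2 to 0.644) with T618I/Q741, and Mcpt1 and the phospholipid transfer gene Pltp (26.7 to 1.82) with T618I/W791, beside Actr3 at 0.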

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

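The tests on the summed stefin A genes, on the specific granule genes and on the erythroid precursor genes were chosen after those results were seen. So were the 3 against 3 comparison and its splits. The tests on scaling, on length and base composition and on the splits of the mutant libraries were set before their values were computed.

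The stefin A genes, S100a8 and S100a9 were higher in every T618I-containing library than in every other. Reads traded between near-identical stefin A copies could raise single genes. The 9 called genes of the cluster, summed, differed 204-fold between the lowest T618I-containing and the highest truncation library. Trading among those 9 would not produce this. They had been called for a class difference and copies not called were left out of the sum, so trading with such copies was not tested. A shift of the FPKM scale by a few abundant genes could change values too. The median log2 difference of the genes called higher was, however, 4.03 with median-ratio scaling and 3.98 without it. More cells at the specific granule stage may be a cause and stay open, as does an untested effect of T618I within cells: the median of Ltf, Camp and Ngp was 1.12 on W791 and 3.43 on Q741. In the T618I library it was -0.0537 beside 3.22 for S100a8, but the other secondary and tertiary granule genes had a median of 1.20 there, with Lcn2 at 628 against 109 FPKM and Cd177 at 24.0 against 2.72.

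Cell cycle genes had medians of opposite sign when T618I was added to Q741 (median -0.74) and to W791 (median 0.39), a difference that was not tested. A bias from transcript length or GC content could produce such a gap, but after removal of these trends the gap between the medians was 0.844 against 1.13 before. Scaling between libraries could also do so, but with median-ratio scaling the medians stayed at -0.55 and 0.40. Whether proliferation differed between the constructs or between these cultures stays open with 1 library each.

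Erythroid genes were higher in each T618I-containing library. Carry-over of mature red cell RNA could raise globin genes alone. Gata1, Klf1, Epor and Car2, which are genes of erythroid precursors, had a median class log2 difference of 1.81, so the rise was not confined to globin genes. Gata1, Klf1 and Epor belong to the erythroid list, whose 16 tested members had all been seen above 0. The value was thus not a separate test, and it does not exclude carry-over. A larger share of erythroid precursors in the sorted cells may fit that value, and a change within cells was not told apart from it.

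For the 22 genes called between the mutant classes, the other 9 of the 10 splits of the mutant libraries gave at most 2 calls, and 1 of 10 splits reached the real count; the splits are too few for a share under 0.05. For the 3 against 3 comparison with 97 calls, 1 of 10 splits reached that count and the highest other gave 2; these splits too are too few for a share under 0.05.

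Granulocytic transcription factors had a median of 0.45 when T618I was added to Q741 and -0.43 on W791, a difference that was not tested. ERK pathway targets had 0.38 and -0.86 in the same pairs, also not tested. The 3 stromal and endothelial genes had 0.46 and -0.34, also not tested. There were 26 genes higher on Q741 and lower on W791 by 2-fold or more each and 4 genes the other way, without a test of the difference. A gene named only by a date averaged 10.2 FPKM in T618I-containing libraries (6.32, 14.9 and 9.43 with T618I, T618I/Q741 and T618I/W791) against 1.85, 2.38 and 2.25 with vector, W791 and Q741, and was not tested because its symbol was lost.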

How the results depend on the processing

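The 3 against 3 comparison and the estimated correlation in it and in fits with a library left out were chosen after the results were seen; the other alternatives were set before. Between the mutant classes, the 20 higher genes became 3 without the filter on low values, 83 with the tail as a block over 3 pairs, 146 over the 2 truncation pairs, 75 in the 3 against 3 comparison and from 2 to 30 with a library left out. The 2 lower genes became 36, 68 and 22 in those fits and from 0 to 5 with a library left out. Of the 22 calls all were kept in the additive and 3 against 3 fits and without a trend, 21 with a pseudocount of 0.1 or a filter at 5 FPKM, 19 with quantile normalization, 18 with median-ratio scaling and 3 without a filter, and 12, 20, 18, 6 and 2 with T618I, T618I/Q741, T618I/W791, W791 or Q741 left out, and 0 reversed. Against vector, the 15 higher genes became 6 without a filter and from 6 to 28 with a library left out, and the 3 lower genes 16 without a filter, 0 with the filter at 5 FPKM, 1 with median-ratio scaling and from 0 to 6 with a library left out. For truncations against vector, 0 became 9 without a filter. The 12 lists called became 0 with an estimated correlation and 0 with fry, and the lists called with a library left out or in the 3 against 3 comparison likewise 0 with an estimated correlation. With a pseudocount of 0.1 and with thresholds of 1.5-fold and 4-fold, the 155 genes higher in both truncation pairs became 237, 308 and 47 and the 89 lower 170, 290 and 6; the 25 genes higher with both truncations on T618I became 47, 70 and 0 and the 59 lower 120, 220 and 5. List medians that changed sign were those of primary granule genes (-0.0421 with quantile normalization, from -0.0352 to 0.11 with a library left out), granulocytic transcription factors (0.0420 with median-ratio scaling, -0.19 to 0.21), the unfolded protein response (0.00213 with quantile normalization and 0.0478 with median-ratio scaling, -0.0584 to 0.10, with 0.0483 when W791 was left out), JAK-STAT targets (-0.0220 to 0.32), ERK pathway targets (-0.42 to 0.19), cell cycle genes (-0.41 to 0.12), Src and Tec family kinases (-0.17 to 0.00703) and cholesterol synthesis genes (-0.00263 to 0.25). The additive fits leave fewer residual degrees of freedom than the class fit, so their larger counts lean more on the prior variance. Class values did not overlap for any of the 22 called genes, so leaving out a library could not reverse a sign. In fits with a library left out the lone member of a group was assumed to vary like the others. With Q741 left out the log2 difference was 9.48 for Stfa2, 7.43 for Stfa2l1, 5.81 for Lipg and 2.90 for S100a8. With all libraries it was 9.79, 8.09, 5.82 and 2.93. Leaving out the filter on low values cannot change a gene's log2 difference, which comes from its own values alone, so the unchanged differences are no sign of stability.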

Other observations

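The list values below for truncations against vector were tests chosen after the results were seen.

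Interferon response genes were below vector in 30 of 30 cases with the truncations alone, with a median of -0.61 (adjusted p = 6.16e-30; adjusted p = 0.401 with an estimated correlation), such as Ifit3 at 2.88 FPKM with W791 and 3.13 with Q741 against 8.98 with vector. Cholesterol synthesis genes were above vector in 18 of 18 cases (median 0.26; adjusted p = 2.53e-08; adjusted p = 0.519 with an estimated correlation), primary granule genes in 14 of 15 (median 0.20; adjusted p = 1.26e-07; adjusted p = 0.219 with an estimated correlation) and JAK-STAT targets in 17 of 20 (median 0.15; adjusted p = 1.56e-06; adjusted p = 0.401 with an estimated correlation). Among the last, Id1 was at 39.9 with W791 and 43.3 with Q741 against 14.3 FPKM with vector, Cish at 9.92 and 10.1 against 4.35, Osm at 77.1 and 61.7 against 31.1 and Socs3 at 85.7 and 73.8 against 45.3. Dendritic and MHC class II genes were below vector in 12 of 13 cases (median -0.53; adjusted p = 3.28e-06; adjusted p = 0.705 with an estimated correlation), Flt3 was at 17.5 and 15.0 against 40.9 FPKM, and Ccnd1 at 17.8 and 17.3 against 39.1. All of these values share 1 vector library, so a property of that library alone would give the same pattern. Nor can introducing a receptor be told apart here from truncating it.

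Arg1 was at 7.13 FPKM with Q741 and 430 with T618I/Q741, and the lists of erythroid, cell cycle and ERK pathway genes also set T618I/Q741 and T618I/W791 apart. T618I/Q741 and T618I/W791 differed by 2-fold or more in 1506 genes, more than any other pair of libraries, so a class mean of T618I-containing libraries hides a large part of what separates them.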
